A study of Mus musculus with 23 samples.

How the data were processed

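Articular cartilage of male CBA and Str/ort mice at 3 labelled ages was collected in RNAlater, and RNA was extracted with QIAzol and a Qiagen mini kit, labelled with biotin by in vitro transcription and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels. There are 23 arrays, 1 per sample, in 5 groups of 4 and 1 group of 3; the number of mice per array is not given. No scan date or batch is given either, so strain and age differences could not be checked for batch. The deposited values are RMA signals on the log2 scale, made by the authors per the submitters' processing notes; the software version is not given in the sources used here. Values lie between 3.11 and 14.7 and array medians between 7.83 and 8.00, and they were used as they are. The number of arrays limits the precision: the median SE of a strain difference was 0.126 at 8 weeks and 0.117 at 18 and 40 weeks.

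Of 34760 transcript clusters, 21640 carry 1 gene, 1321 several and 11799 none. The comparisons use those with 1 gene, and for the 954 genes with several clusters the cluster with the highest mean over all arrays, which leaves 19937 genes. Gene names come from the platform annotation; 21553 Entrez identifiers matched a RefSeq table of GRCm38.p6 and 87 did not, and no symbol was changed. The genome build of the platform annotation is not given in the sources used here, so no coordinates are reported. The RefSeq table served for names and for finding neighbouring genes.

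One linear model with a mean per group was fitted to all 23 arrays with limma 3.58.1 in R 4.3.3 (residual df 17, prior df 4.15). It gave 13 comparisons: Str/ort against CBA at each age and averaged over ages, each pair of ages in each strain, and the 3 differences between the strains' age changes. P values were adjusted by the method of Benjamini and Hochberg and a gene was called at an adjusted p under 0.05. SE are those of the moderated fit. Genes without overlap are called genes for which every array of one group lies above every array of the other.

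Gene lists were written before the data were examined. There are 29 lists with 684 entries of 664 symbols, 624 of them measured and 20 in 2 lists. The 17 pathway lists are cartilage matrix, chondrocyte regulators, superficial zone, hypertrophy and mineralisation, matrix proteases and inhibitors, fibrillar and other collagens, inflammatory mediators, Wnt pathway, TGF-beta and BMP pathway, oxidative phosphorylation, glycolysis, cell cycle, interferon response, immediate early and heat shock, circadian clock, senescence and stress response, and unfolded protein response. The 12 cell type lists are markers of skeletal muscle, osteoblasts and osteocytes, osteoclasts, synovial fibroblasts and tendon, adipocytes, erythroid cells, neutrophils, macrophages, lymphocytes, endothelium, Schwann cells, and pericytes and smooth muscle. Each list was tested with camera from limma with a preset correlation between genes of 0.01, and again with an estimated correlation. Members were also adjusted over the list alone. Markers can be expressed by more than one cell type, so a list measures RNA abundance and not cell numbers.

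The rule for naming genes was set before the data were examined. For a strain comparison at one age it names the 10 largest rises and 10 largest falls among called genes without overlap, for the average and the age comparisons 6 each way, and for the differences between strains 5 each way; predicted and unnamed symbols are passed over. For each list it names up to 4 called members with the largest change, or 2 members where none is called. Col2a1, Acan, Prg4, Col10a1, Mmp13, Adamts5, Adamts4, Mmp3, Sox9, Timp3 and Xist were always tested.

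The pipeline was tested on simulated data, with changes planted in 200 of 19937 genes. At log2 changes of 0.5, 1 and 2 it recovered 46.3%, 92.5% and 100% of the changed genes for the 8 week comparison, 64.2%, 95.5% and 100% for that at 18 weeks and 56.7%, 89.6% and 98.5% for that at 40 weeks. Wrong calls were 10 of 169, 8 of 181 and 7 of 170. A list shifted by 0.5 was called and no other of the 29 was. Simulated values were drawn independently for each gene, so this run does not show how either test behaves where genes vary together.

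The alternatives set before the data were examined were leaving out the dimmest 40% of genes (11963 left), the mean of a gene's clusters, every cluster on its own, quantile normalization, an intensity trend with robust settings, array weights (statmod 1.5.0), the replicate number as a block, the muscle marker mean as a covariate, a fit on the groups of the comparison alone, and leaving out each array in turn. Added after the results were seen were leaving out CBA 8 weeks replicate 1 and CBA 40 weeks replicate 3, the muscle and erythroid means as 2 covariates, and exact permutation tests of list means. Groups of 4 were searched for outlying arrays with Dixon's test, which chance alone meets in 5% of groups. Clusters with several genes or none stayed out of the comparisons because their signal cannot be given to 1 gene.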

Results

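Gene expression was measured in articular cartilage of male mice of 2 strains, Str/ort, which develops osteoarthritis spontaneously with age, and CBA, which does not. Each strain was sampled at 3 ages, labelled 8, 18 and 40 weeks, on 23 Affymetrix arrays. There were 4 arrays per group except for Str/ort at 8 weeks, which had 3; the series design text calls them biological replicates. Array medians lay between 7.83 and 8.00 on the log2 scale. In 21 of the arrays the SD of the difference from the rest of the group, taken across all genes, was 0.146 to 0.306. It was 0.454 in CBA 8 weeks replicate 1 and 0.656 in CBA 40 weeks replicate 3, and the median correlation of these 2 arrays with their own group was 0.9747 and 0.941, against 0.9855 or higher in the others. No pair of arrays held identical values.

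Levels of markers of tissues next to cartilage varied between the samples. The mean log2 level of 40 skeletal muscle markers was between 7.51 and 12.13, with the highest value in CBA 40 weeks replicate 3. The mean of 14 erythroid markers was between 10.92 and 12.27, and that of 20 neutrophil markers between 12.06 and 12.97. The plot of list means shows the muscle and erythroid values per array. Erythroid and neutrophil means lay far above the array median in every array. The strain and age differences below are therefore those of whole samples and cannot be assigned to cartilage cells. Of the canonical cartilage genes, Prg4, which encodes the joint lubricant lubricin, lay between 13.18 and 13.74 in every array, Col2a1, the main cartilage collagen, between 9.32 and 11.38, and Acan, the core protein of aggrecan, between 8.72 and 12.23. Xist, expressed from the inactive X chromosome of females, was between 5.72 and 6.33 in all arrays except Str/ort 8 weeks replicate 1, where it was 7.76.

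**Figure D1:**
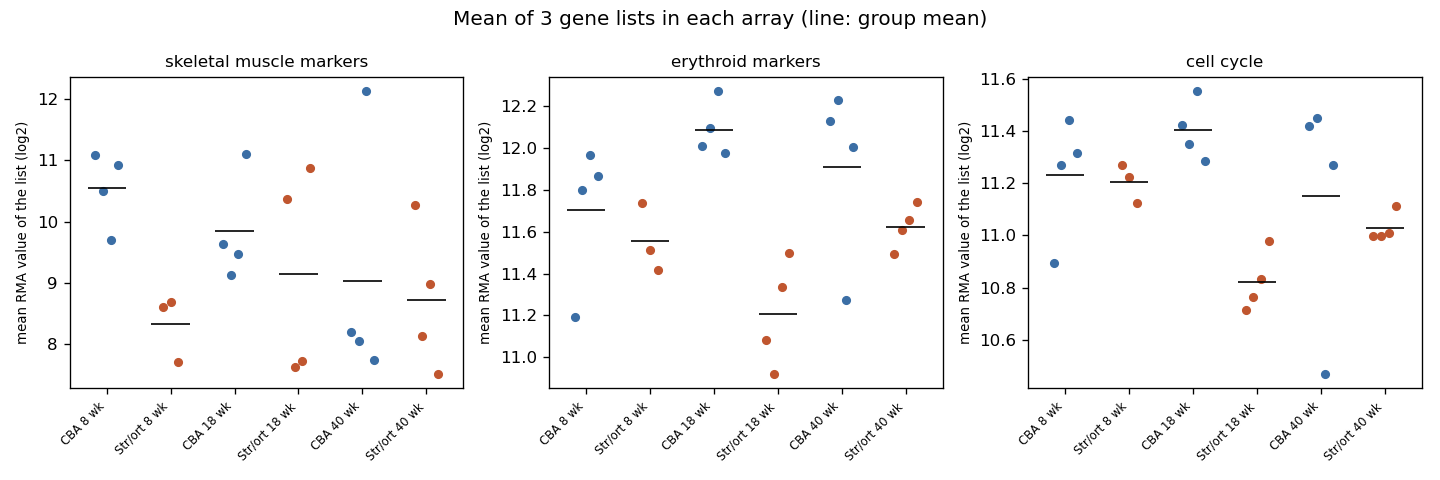
Mean RMA value (log2) of the skeletal muscle, erythroid and cell cycle lists in each array, with a line at each group mean. The muscle mean of CBA 40 weeks replicate 3 was 12.13, and the erythroid means of the 4 Str/ort arrays at 18 weeks were 10.92 to 11.50, all under the 4 CBA arrays of that age at 11.98 to 12.27.

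The first question was how the cartilage samples of the 2 strains differ at 8 weeks (n = 3 Str/ort and 4 CBA arrays). Gdpd3, a lysophospholipase D, was higher in Str/ort by a log2 fold change of 4.14 ± 0.14 (SE), Trim12a by 3.88 ± 0.17, the complement protease gene C1s1 by 3.83 ± 0.57, the mast cell protease gene Mcpt2 by 3.62 ± 0.20, Trim30d by 3.58 ± 0.18 and Ly6a2 by 3.20 ± 0.19. H2-Ea, the alpha chain of the MHC class II E molecule, was lower in Str/ort, at -5.84 ± 0.19 (adjusted p = 7.78e-15). The eosinophil-associated ribonuclease Rnase2a (2.03 ± 0.27) and the complement gene C4b (1.88 ± 0.23) were higher. Of the interferon-inducible p200 family, Ifi202b was higher (1.73 ± 0.25) while Ifi214 (-2.27 ± 0.17) and Ifi209 (-1.59 ± 0.24) were lower. Serpina3b (-1.87 ± 0.31), St8sia1, which makes ganglioside GD3 (-1.67 ± 0.13), Ttc9 (-1.63 ± 0.17), the alcohol dehydrogenase gene Adh1 (-1.58 ± 0.16) and Padi2, a protein-citrullinating enzyme (-1.51 ± 0.24), were also lower.

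Among the fixed gene lists at 8 weeks, the interferon response stood highest in Str/ort, with a median of 0.54 over 23 genes. Of its members 5 were higher, none was lower and 18 were not called, and 16 were called when adjusted over the list alone. Ifit1, an interferon-induced RNA-binding protein, was higher by 1.27 ± 0.24 and kept its call whichever array was left out. Rtp4 (1.18 ± 0.30, adjusted p = 0.0495) lost its call in 6 of 7 such fits, all but that without Str/ort replicate 1 (highest adjusted p = 0.289), and Oas2 (0.97 ± 0.24) lost its call without CBA replicates 1, 2 or 4 or Str/ort replicates 2 or 3 (highest adjusted p = 0.24). Of 26 matrix proteases and inhibitors 1, Htra1, a serine protease that degrades matrix proteins, was higher (1.17 ± 0.27), and 11 were called over the list alone, all higher. Htra1 lost its call without CBA replicates 1 or 2 or Str/ort replicates 1 or 3 (highest adjusted p = 0.169). Of 22 collagens and related matrix genes none was called over all genes and 7 were over the list alone, all higher, with a median of 0.38. The TGF-beta receptor gene Acvrl1 was higher by 0.74 ± 0.13. Cd3d, part of the T cell receptor complex, was lower by a log2 value of -1.35 ± 0.21, while the tendon and fibroblast gene Fibin was higher by 1.55 ± 0.30 and lost its call without Str/ort replicate 3 (adjusted p = 0.0887) and, at 0.91, with the muscle and erythroid means as covariates. Alongside these, the skeletal muscle markers had a median difference of -2.56 over 40 genes, none of them called over all genes or over the list alone. Limma's camera test called 13 of the 29 lists at 8 weeks, 10 higher and 3 lower, among them the interferon response (adjusted p = 1.64e-10) and muscle markers (adjusted p = 3.26e-13). None of the 13 calls was kept with an estimated correlation, where the lowest was adjusted p = 0.73 and 1 list had an unadjusted p under 0.05.

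In all, 347 of 19937 genes were called at 8 weeks by limma, 241 higher and 106 lower in Str/ort. The count was 771 without CBA 8 weeks replicate 1 and CBA 40 weeks replicate 3, a choice made after seeing the data, and 334 of the 347 were kept. With array weights it was 1421. It was 197 without CBA replicate 2, 180 without Str/ort replicate 2 and 140 without Str/ort replicate 3. Of the 36 called genes named by rule, 20 kept their call whichever array was left out.

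**Figure D2:**
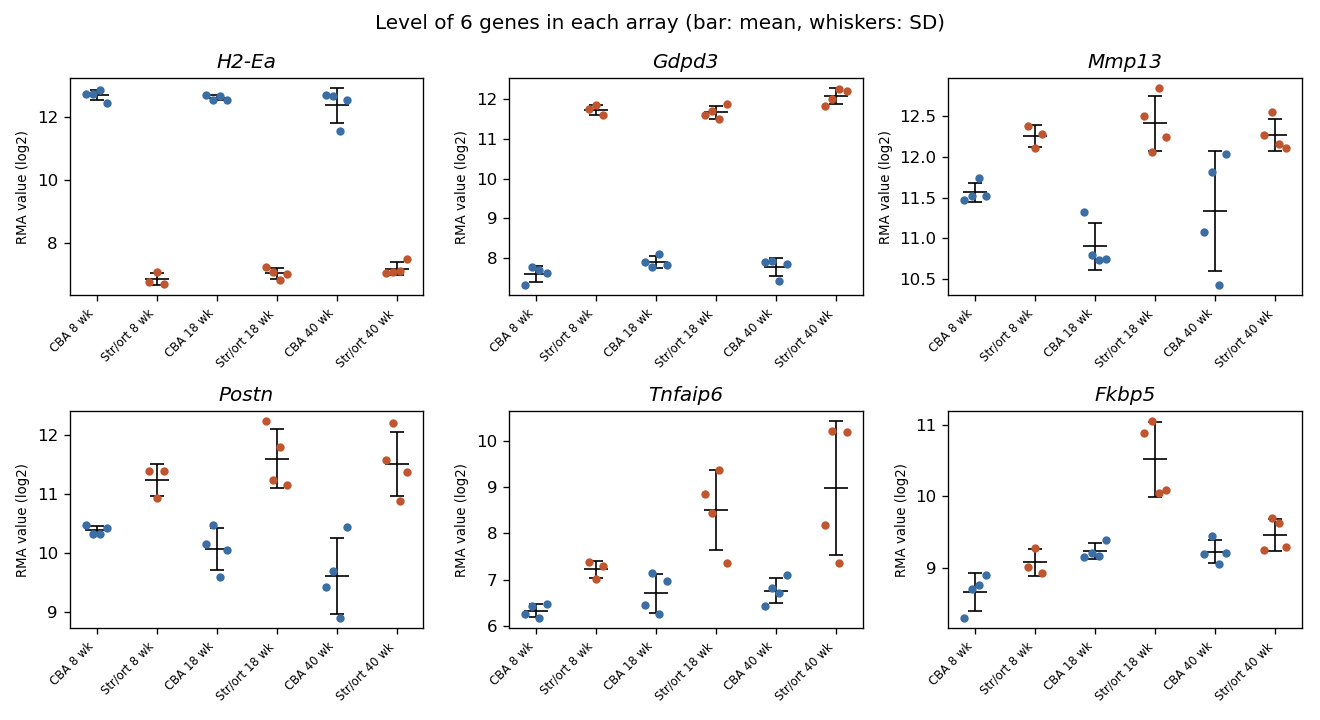
RMA value (log2) of 6 genes in each array by strain and age, with the group mean (bar) and SD (whiskers). H2-Ea was lower in Str/ort by log2 values of -5.84, -5.57 and -5.19 at 8, 18 and 40 weeks, and Gdpd3 was higher by 4.14, 3.78 and 4.32.

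At 18 weeks (n = 4 arrays per strain) genes of the extracellular matrix and its turnover were higher in Str/ort. Mmp13, the collagenase that cleaves type II collagen, was higher by 1.51 ± 0.24 (adjusted p = 0.000501), Postn, which encodes the matricellular protein periostin, by 1.54 ± 0.29, Timp1, an inhibitor of matrix metalloproteinases, by 1.48 ± 0.31, Col6a3 by 1.38 ± 0.24 and Col6a1 by 1.09 ± 0.22. At 8 weeks Mmp13 was at 0.69 ± 0.26 and not called (adjusted p = 0.194). From 8 to 18 weeks Mmp13 changed by -0.66 ± 0.24 in CBA and by 0.15 ± 0.26 in Str/ort, without a call in either. Of 22 collagens and related matrix genes 14 were higher, none was lower and 8 were not called, with a median of 0.57, and 18 were called over the list alone. Of 26 matrix proteases and inhibitors 7 were higher and 19 were not called, and 12 were called over the list alone. Camera called both lists (adjusted p = 1.45e-13 and 0.00000341), with adjusted p = 0.419 and 0.506 with an estimated correlation. Sox6, a transcription factor of chondrocytes, was lower at -0.61 ± 0.10, while Sox9 (0.55 ± 0.25), Col2a1 (0.37 ± 0.26), Acan (0.74 ± 0.47), Col10a1 (0.49 ± 0.37), Mmp3 (0.99 ± 0.35), Adamts4 (0.48 ± 0.17), Adamts5 (0.43 ± 0.18), Timp3 (0.29 ± 0.18) and Prg4 (0.20 ± 0.10) were not called. With single arrays left out Col2a1 ranged from 0.06 (without Str/ort replicate 3) to 0.51, Acan from 0.44 (without Str/ort replicate 2) to 1.16, Col10a1 from 0.25 (without Str/ort replicate 3) to 0.80, Sox9 from 0.36 to 0.80, Mmp3 from 0.64 to 1.31, Adamts4 from 0.30 to 0.59, Adamts5 from 0.24 to 0.55 and Timp3 from 0.12 to 0.44. Of these, Sox9, Mmp3 and Adamts4 were called without Str/ort replicate 4, Mmp3 also without CBA replicate 2, and Mmp3, Adamts4 and Adamts5 without the 2 arrays that stood apart. With the muscle and erythroid means as covariates Mmp13 kept its call, Postn (1.39, SE 0.47), Timp1 (1.03, SE 0.41), Col6a3 (1.16, SE 0.39), Col6a1 (0.99, SE 0.36) and Sox6 (-0.27, SE 0.14) lost theirs, and Sox9 (-0.31), Acan (-0.26) and Col10a1 (-0.60) were below 0. The erythroid means of the strains do not overlap at this age, so that fit carries a slope from within the groups across a gap between them, and the median SE over all genes is 0.163 in place of 0.117. The arrays farthest from their groups on the erythroid mean are CBA 40 weeks replicate 3 (11.27) and CBA 8 weeks replicate 1 (11.19), which stood apart. The slope leans on them, and the fit with both covariates was not run without them.

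Genes of blood formation and of cell division were lower in Str/ort at 18 weeks. All 14 measured erythroid markers were lower, with a median of -0.90, among them Epb42, a red cell membrane protein (-1.15 ± 0.22), Trim10 (-1.14 ± 0.25) and Tspan33 (-1.05 ± 0.24). Of 29 cell cycle genes 21 were lower, none was higher and 8 were not called, and 28 were called over the list alone, with a median of -0.59. Tk1, a thymidine kinase of dividing cells, was at -0.72 ± 0.17 and lost its call without CBA replicate 3 (adjusted p = 0.054). Camera called both lists (adjusted p = 1.1e-14 and 5.2e-16), with adjusted p = 0.419 and 0.506 with an estimated correlation. The T cell genes Cd3d (-1.75 ± 0.20) and Cd3g (-1.37 ± 0.21), the integrin gene Itgad (-1.98 ± 0.19), the macrophage scavenger receptor gene Cd163 (-1.61 ± 0.27), Cd209f (-2.46 ± 0.39) and Ccr3, the eotaxin receptor of eosinophils (-2.66 ± 0.28), were lower. Of 18 adipocyte markers 4 were lower and 14 not called, and 7 were called over the list alone, with a median of -0.42 and adjusted p = 0.579 with an estimated correlation. Over the same arrays the muscle markers had a median difference of -0.74, with none called, and 20 neutrophil markers one of 0.11, with 1 higher and 1 lower. With the muscle and erythroid means as covariates Tk1 (-0.14, SE 0.14), Cd3g (-0.82, SE 0.24), Cd163 (-0.97, SE 0.39) and Cd209f (-1.77, SE 0.58) lost their call; the erythroid markers are part of the covariate, so that fit is no test of them.

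The chemokine genes Ccl2 (0.87 ± 0.15) and Ccl7 (0.70 ± 0.13), the oncostatin M receptor gene Osmr (0.87 ± 0.16), the Wnt receptor gene Fzd1 (0.68 ± 0.11), Ltbp2, which binds latent TGF-beta (0.65 ± 0.13), and Oas2 (1.22 ± 0.22) were higher at 18 weeks. The clock genes Per1 (0.91 ± 0.17) and Nfil3 (0.50 ± 0.09) were higher and Dbp (-0.53 ± 0.12) was lower. Of 15 osteoclast markers 4 were higher, among them the cell fusion gene Dcstamp (0.75 ± 0.17), 1, Car2, was lower (-0.70 ± 0.14), and 10 were not called; 7 were called over the list alone. Car2 encodes a carbonic anhydrase that red cells also contain. Camera called the osteoclast list (adjusted p = 0.0219), with adjusted p = 0.593 with an estimated correlation. Of 22 senescence and stress response genes 6 were lower and 16 not called, and 8 were called over the list alone, with the catalase gene Cat at -0.54 ± 0.12 (adjusted p = 0.548 for the list with an estimated correlation). Of the 12 genes named here only Osmr and Nfil3 kept their call with the muscle and erythroid means as covariates, where Oas2 was at 1.23, Dbp at -0.72, Ccl2 at 0.70, Dcstamp at 0.69, Ltbp2 at 0.63, Ccl7 at 0.50, Fzd1 at 0.46, Per1 at 0.42, Car2 at -0.01 and Cat at -0.20, with SE from 0.11 to 0.36.

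Limma called 1742 of 19937 genes at 18 weeks, 541 higher and 1201 lower in Str/ort. It called 221 with the muscle and erythroid means as covariates, 2661 with the muscle mean alone, 4169 when fitted on the 2 groups alone and 6218 with array weights. Without the 2 arrays that stood apart, both from other groups and removed only after seeing the data, 5150 genes were called, including all 1742. The count was 1069 without CBA replicate 1, 687 without CBA replicate 3, and 881, 1006 and 1053 without Str/ort replicates 1, 2 and 3. Of the 29 lists 18 were called, 12 higher and 6 lower, and none with an estimated correlation (lowest adjusted p = 0.419, 2 lists with an unadjusted p under 0.05). Of the 91 called genes named by rule, 45 kept their call whichever array was left out.

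**Figure D3:**
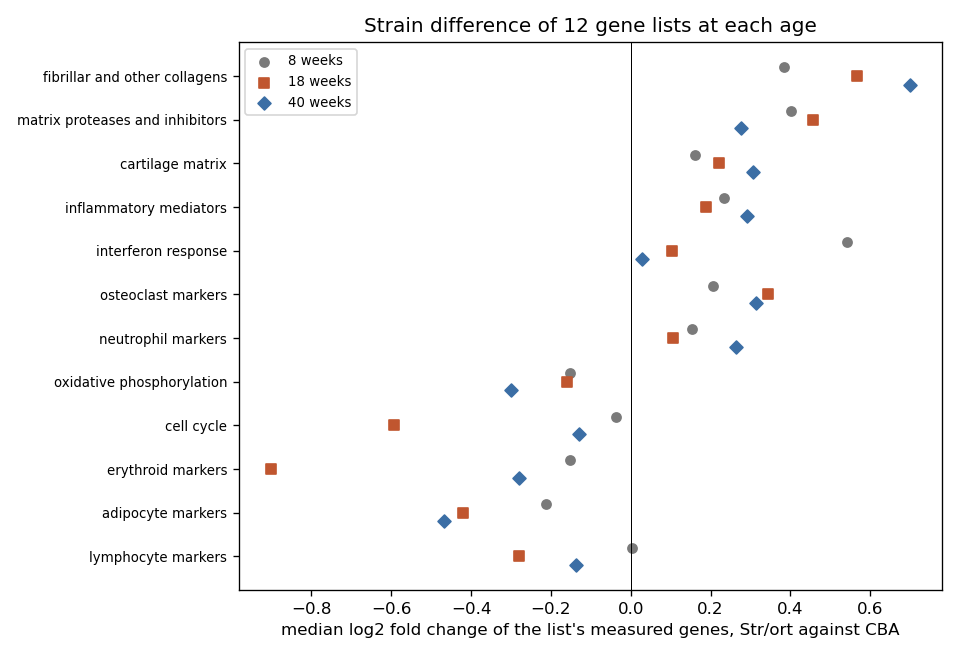
Median log2 fold change of 12 gene lists, Str/ort against CBA, at 8, 18 and 40 weeks. The collagen list was above 0 at each age, at 0.38, 0.57 and 0.70, and the interferon response was at 0.54, 0.10 and 0.03.

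At 40 weeks (n = 4 arrays per strain) the collagen list again had the highest median of the matrix lists, 0.70. Of its 22 genes 8 were higher, none was lower and 14 were not called, and 17 were called over the list alone. Postn was higher by 1.90 ± 0.29 and Col12a1 by 1.32 ± 0.28 (adjusted p = 0.000383 and 0.00801), and camera gave the list adjusted p = 3.16e-13, or adjusted p = 0.408 with an estimated correlation. Tnfaip6, a hyaluronan-binding protein induced by inflammatory cytokines, was higher by 2.22 ± 0.47, Ccl2 by 1.08 ± 0.15, Ccl7 by 0.72 ± 0.13, and Chit1, a chitinase of activated macrophages, by 1.88 ± 0.16. Of 24 inflammatory mediators these 2 chemokines were higher and 22 were not called, and 12 were called over the list alone, with a median of 0.29 and adjusted p = 0.408 with an estimated correlation. Mmp13 was higher by 0.93 ± 0.24 (adjusted p = 0.0329). It kept that call only without CBA replicates 2 or 4, and without CBA 40 weeks replicate 3 its difference was 0.63 (adjusted p = 0.0509). Timp1 was higher by 1.32 ± 0.31 and lost its call without Str/ort replicates 2 or 4 (highest adjusted p = 0.0664). The medians of the collagens and of the inflammatory mediators were 0.45 and 0.17 without the 2 arrays that stood apart.

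Fabp4, a fatty acid carrier of adipocytes, was lower in Str/ort at 40 weeks, at -1.20 ± 0.22, as were the glycerol 3-phosphate dehydrogenase gene Gpd1 at -1.85 ± 0.40 and Cyp2f2, a cytochrome P450, at -1.93 ± 0.39. Of 18 adipocyte markers 4 were lower and 14 not called, and 10 were called over the list alone, with a median of -0.47 and adjusted p = 0.466 with an estimated correlation. Of 32 oxidative phosphorylation genes none was called over all genes and 15 were over the list alone, all lower, with a median of -0.30 (camera adjusted p = 3.76e-10, or adjusted p = 0.466 with an estimated correlation). Without the 2 arrays that stood apart the median of that list was -0.16 and 4 of its genes were called. The muscle markers had a median difference of -0.25 with all arrays and 0.74 without those 2, with none called in either. Cd163 (-1.41 ± 0.27), Mertk, a receptor for uptake of dead cells (-0.82 ± 0.17), Cd3d (-1.49 ± 0.20), the superficial zone gene Igfbp5 (-0.77 ± 0.16), Sox6 (-0.51 ± 0.10) and Dbp (-0.69 ± 0.12) were lower, while the macrophage scavenger receptor gene Msr1 (0.98 ± 0.21) and the neutrophil granule gene Camp (0.82 ± 0.14) were higher. Of 14 erythroid markers 1 was lower, with a median of -0.28 and 2 called over the list alone. Without the 2 arrays that median was -0.50 with 13 lower, and 24 of 29 cell cycle genes were lower against none with all arrays.

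Limma called 714 genes at 40 weeks, 243 higher and 471 lower in Str/ort, or 445 higher and 485 lower after quantile normalization. It called 3929 without the 2 arrays that stood apart, including 711 of the 714, 1700 without CBA 40 weeks replicate 3 alone, 472 without Str/ort replicate 3, 4624 with array weights, 1111 with the muscle mean and 2032 with the muscle and erythroid means as covariates, and 189 when fitted on the 2 groups alone. In the last fit, which leaves every difference the same and changes only its error, Col12a1, Tnfaip6, Mmp13, Timp1, Gpd1, Cyp2f2, Cd163, Mertk, Igfbp5, Sox6 and Msr1 lost their call. Of the lists 17 were called, 11 higher and 6 lower, and none with an estimated correlation (lowest adjusted p = 0.408, 2 lists with an unadjusted p under 0.05). Col2a1 (0.81 ± 0.26, adjusted p = 0.0885), Acan (1.23 ± 0.47), Col10a1 (1.11 ± 0.37), Sox9 (0.66 ± 0.25), Mmp3 (0.81 ± 0.35), Adamts4 (0.42 ± 0.17), Timp3 (0.20 ± 0.18), Prg4 (0.14 ± 0.10) and Adamts5 (-0.02 ± 0.18) were not called at this age. Without CBA 40 weeks replicate 3 Acan was at 0.75, Prg4 at 0.09, Timp3 at 0.02 and Adamts5 at -0.11, and without CBA 40 weeks replicate 4 Col10a1 was called, at 1.39.

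Averaged over the 3 ages (n = 11 Str/ort and 12 CBA arrays), the strain difference was called for 3009 genes, 1458 higher and 1551 lower in Str/ort. Gdpd3 (4.08 ± 0.08), Trim12a (3.69 ± 0.09), Mcpt2 (3.64 ± 0.11), Ly6a2 (3.56 ± 0.10), Trim30d (3.07 ± 0.10) and Rnase2a (2.02 ± 0.15) were the highest by rule, and H2-Ea (-5.53 ± 0.11), Adh1 (-2.03 ± 0.09), Ccr3 (-1.99 ± 0.17), Serpina3b (-1.88 ± 0.17), Ifi214 (-1.84 ± 0.10) and Ttc9 (-1.77 ± 0.09) the lowest. These 12 kept their call whichever array was left out. At all 3 ages 90 genes were called higher and 66 lower, 2110 were called at some age, and none was called in opposite directions at different ages. The 8 and 18 week comparisons, which share no arrays, had 129 higher and 72 lower genes in common, where independent lists of those sizes would share 6.54 and 6.39. Across all genes, which are not independent replicates, their differences had r = 0.33 and rho = -0.025, so their ranks did not follow each other. The 18 and 40 week comparisons shared 159 higher and 314 lower genes (6.59 and 28.4 for independent lists), and those at 8 and 40 weeks 102 and 73 (2.94 and 2.50), with rho = 0.66 and 0.19 across all genes. All comparisons use one variance estimate per gene, which adds to such overlaps.

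Across ages, 4 of 27 cartilage matrix genes were higher in Str/ort and 23 were not called, with the proteoglycan gene Vcan at 0.82 ± 0.11 and the collagen gene Col11a1 at 0.51 ± 0.11. Acan, at 0.89 ± 0.28 (adjusted p = 0.033), lost its call without CBA 8 weeks replicate 3, Str/ort 8 weeks replicates 1 or 3, CBA 18 weeks replicate 3, Str/ort 18 weeks replicates 2 or 3 or Str/ort 40 weeks replicate 1 (highest adjusted p = 0.0904). Col2a1, at 0.40 ± 0.15 (adjusted p = 0.0891), and Prg4, at 0.17 ± 0.06, were not called. Of 18 chondrocyte regulators 3 were higher and 1 lower, including Trps1 (0.42 ± 0.09) and Sox6 (-0.44 ± 0.06). Sox9, the master regulator of chondrocytes, was at 0.44 ± 0.15 (adjusted p = 0.0484) and lost its call in 18 of the 23 fits that left out an array, all but those without CBA 8 weeks replicate 1, Str/ort 8 weeks replicate 2, Str/ort 18 weeks replicates 1 or 4 or CBA 40 weeks replicate 4 (highest adjusted p = 0.118). Of 18 superficial zone genes 3 were higher and 1 lower, including the hyaluronan receptor gene Cd44 (0.38 ± 0.07). Of 19 hypertrophy and mineralisation genes 5 were higher and 1 lower, including Col10a1, the collagen of hypertrophic chondrocytes (0.80 ± 0.22), and the phosphatase gene Alpl (0.52 ± 0.11). Of 26 matrix proteases and inhibitors 16 were higher and none lower, including Mmp13 (1.04 ± 0.14), Timp1 (1.31 ± 0.18), Htra1 (1.00 ± 0.15), Mmp3 (0.78 ± 0.21) and the aggrecanase gene Adamts4 (0.36 ± 0.10). Of 22 collagens and related genes 18 were higher and none lower, including Postn (1.43 ± 0.17) and Col6a3 (0.98 ± 0.14). Counts adjusted over the list alone were 10, 4, 6, 8, 18 and 20 for these 6 lists in order. With an estimated correlation their camera adjusted p = 0.377, 0.446, 0.446, 0.377, 0.305 and 0.305 in the same order. With the muscle and erythroid means as covariates Col10a1 was at -0.02, Sox9 at -0.16, Acan at 0.11 and Adamts4 at 0.09, and these lost their call, as did Col11a1 (0.37), Trps1 (0.23), Sox6 (-0.24), Alpl (0.34) and Mmp3 (0.46); the median SE over all genes was then 0.0974 in place of 0.0692. Acan (0.55), Sox9 (0.26) and Col10a1 (0.49) also lost it with the muscle mean alone, and Prg4 gained one in 5 of the 23 fits that left out an array.

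Among signalling and metabolic lists averaged over ages, 11 of 24 inflammatory mediators were higher, including Ccl2 (0.81 ± 0.09), Il1b (0.71 ± 0.20) and Osmr (0.66 ± 0.09), and 2 lower, including Ccl5 (-0.66 ± 0.11). Of 33 Wnt pathway genes 5 were higher, including the Wnt inhibitor gene Dkk1 (0.50 ± 0.14), and of 36 TGF-beta and BMP pathway genes 8 were higher, including Acvrl1 (0.65 ± 0.07), with none lower in either list. Interferon response genes were higher in 8 of 23 cases and lower in none (Oas2, 0.90 ± 0.13), immediate early and heat shock genes higher in 8 of 28 (Gadd45b, 0.37 ± 0.07), and unfolded protein response genes higher in 8 of 23 (the disulfide isomerase gene Pdia6, 0.51 ± 0.11). Of 32 oxidative phosphorylation genes 7 were lower, including Sdhb (-0.46 ± 0.11), and of 29 cell cycle genes 9 were lower, including the proliferation marker gene Mki67 (-0.33 ± 0.07). Of 17 glycolysis genes 3 were higher and 2 lower (the glucose transporter gene Slc2a1, 0.55 ± 0.11), of 18 circadian clock genes 2 were higher and 4 lower (Dbp, -0.48 ± 0.07), and of 22 senescence and stress response genes 1 was higher and 5 lower (Hmox1, -0.72 ± 0.14). Counts adjusted over the list alone were 15, 5, 10, 11, 11, 10, 19, 19, 5, 6 and 8 for these 11 lists in order. Of these, camera did not call the Wnt, glycolysis and circadian lists (adjusted p = 0.0868, 0.49 and 0.49), and with an estimated correlation the lowest was adjusted p = 0.334. With the muscle and erythroid means as covariates Dkk1 (0.53), Mki67 (-0.13), Slc2a1 (0.31) and Hmox1 (-0.49) lost their call, and Il1b was at 1.51. An average can rest on single ages. From 8 to 18 weeks the strain difference moved by a median of -0.44 for the interferon list and -0.58 for the cell cycle list. No gene was called for those shifts.

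Of the skeletal muscle markers 0 of 40 were called by limma for the strain average, with a median of -1.22 and camera adjusted p = 0.00000227. Of 17 osteoblast and osteocyte markers 9 were higher (Ibsp, 0.52 ± 0.11), of 15 osteoclast markers 7 were higher and 1 lower (the collagen-degrading protease gene Ctsk, 0.61 ± 0.16), and of 20 synovial fibroblast and tendon markers 9 were higher (Fibin, 1.32 ± 0.17). Of 18 adipocyte markers 10 were lower (Cidec, -1.13 ± 0.22), of 14 erythroid markers 11 were lower (Sptb, -0.53 ± 0.10), and of 18 lymphocyte markers 4 were lower (Cd3d, -1.53 ± 0.12). Of 20 neutrophil markers 8 were higher and 1 lower (Camp, 0.66 ± 0.08; Ly6g, -0.50 ± 0.06), and of 20 macrophage markers 7 were higher and 3 lower (Msr1, 0.78 ± 0.13; Cd163, -1.39 ± 0.16). Of 20 endothelial markers 1 was higher and 2 lower, of 12 Schwann cell markers 3 were higher and 1 lower, and of 15 pericyte and smooth muscle markers 2 were higher and 1 lower. Counts adjusted over the list alone were 0, 13, 12, 10, 14, 14, 4, 10, 10, 5, 7 and 3 for these 12 lists in order. Camera called 22 of all 29 lists for the strain average, 15 higher and 7 lower, and not those of macrophages, endothelium, Schwann cells or pericytes (adjusted p = 0.107, 0.922, 0.395 and 0.258). None of the 22 was kept with an estimated correlation (lowest adjusted p = 0.305, 3 lists with an unadjusted p under 0.05). With the muscle and erythroid means as covariates Ibsp (0.47) and Ctsk (0.42) lost their call. These averages need not hold equally at each age. At 8 weeks the erythroid means were 11.42 to 11.73 in Str/ort, 11.19 in CBA replicate 1 and 11.8 to 11.96 in the other CBA arrays. The strains thus overlapped at 8 weeks through that CBA array, which stood apart.

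The count of genes for the strain average was 4617 without CBA 8 weeks replicate 1 and 7004 without both arrays that stood apart, including 2989 of the 3009. It was 7857 with array weights and 1906 with the muscle and erythroid means as covariates, and quantile normalization gave 2000 higher and 1628 lower genes. Of the 121 called genes named by rule, 99 kept their call whichever array was left out. Trim12a, Trim30d, Ly6a2, C1s1, Mcpt2, Rnase2a, Serpina3b and the p200 genes belong to multigene families whose members can share probe sequence, so signal from relatives may be included in their values, which was not tested.

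**Figure D4:**
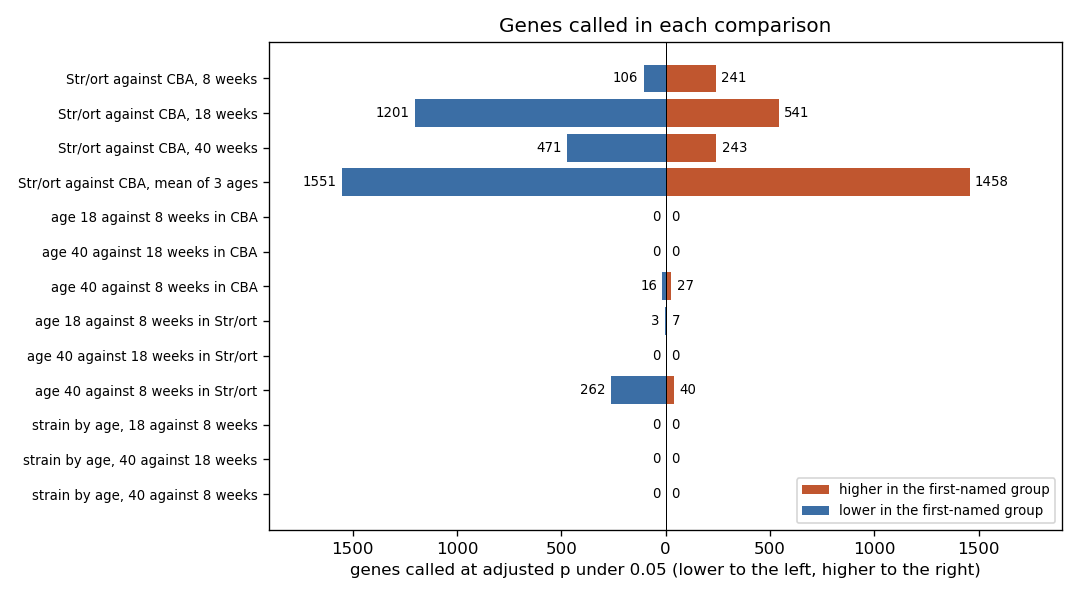
Number of genes called at adjusted p under 0.05 in each comparison, higher to the right and lower to the left. The strain comparisons gave 347, 1742 and 714 genes at 8, 18 and 40 weeks and 3009 on average, the age comparisons at most 302.

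The next question was what changes with age in CBA, the strain without spontaneous disease (n = 4 arrays per age). From 8 to 40 weeks Jchain, which joins antibody units in plasma cells, rose by 1.47 ± 0.21 (adjusted p = 0.00753). Rag2, a recombinase subunit of immature lymphocytes, fell by 0.85 ± 0.13, and Ifi214 by 1.09 ± 0.16. These 3 kept their call whichever array was left out, and were the only ones of 14 called genes named by rule to do so. The light chain gene Igkv6-20 (1.63 ± 0.30), the steroid dehydrogenase gene Hsd3b6 (1.502 ± 0.241) and Adh1 (0.83 ± 0.14) also rose. Il2ra (-0.98 ± 0.18), Il7r, the interleukin 7 receptor (-0.90 ± 0.18), Vpreb3 (-0.92 ± 0.19) and Igll1, a surrogate light chain of pre-B cells (-0.85 ± 0.18), the stem cell marker gene Lgr5 (-0.81 ± 0.14) and the fibroblast protease gene Fap (-0.84 ± 0.15) fell. Of 18 lymphocyte markers 1 rose, 2 fell and 15 were not called, and 5 were called over the list alone, with a median of -0.27. The muscle markers had a median change of -1.61 over the same arrays, with none called. These medians were -0.08 and -2.675 without the 2 arrays that stood apart, where camera did not call the lymphocyte list and the muscle genes Casq1 (-3.78) and Myot (-3.98) were called. Il7r, Vpreb3 and Igll1 were then at -0.58, -0.61 and -0.53, still called. Camera called 10 lists, including these 2 (adjusted p = 0.0029 and 7.13e-11), and none with an estimated correlation (lowest adjusted p = 0.768, 0 lists with an unadjusted p under 0.05).

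Limma called 43 genes between 8 and 40 weeks in CBA, 27 higher and 16 lower, and 0 when fitted on these 2 groups alone, which leaves every difference the same. With array weights it called 1410, with the muscle mean as a covariate 461, with the muscle and erythroid means 1298, after quantile normalization 88 and without the dimmest genes 79. Single arrays decided this count: it was 16, 4, 5 and 77 without CBA 8 weeks replicates 1, 2, 3 and 4, and 10, 1620 and 5 without CBA 40 weeks replicates 2, 3 and 4. The named genes other than Jchain, Rag2 and Ifi214 each lost their call without CBA 8 weeks replicate 2, and in 2 to 6 of those fits in all, with adjusted p up to 0.169. It was 954 without both arrays that stood apart, including all 43. Camera called 6 lists without CBA 40 weeks replicate 3. Between 8 and 18 weeks limma called 0 genes, with 3507 at an unadjusted p under 0.05 where 997 are expected without any change, 5 without CBA 8 weeks replicate 4 and 188 without the 2 arrays. Erythroid markers had a median of 0.43 in that interval (0.24 without the 2 arrays), with 1 of 14 called over the list alone. Between 18 and 40 weeks it called 0 genes, with 767 at an unadjusted p under 0.05, 2 without CBA 40 weeks replicate 3 and 3 without the 2 arrays. Camera called 11 and 13 lists in the 2 intervals, the latter 8 without CBA 18 weeks replicate 4 and 21 without CBA 40 weeks replicate 4, and none with an estimated correlation (lowest adjusted p = 0.772 and 0.711, 0 and 1 lists with an unadjusted p under 0.05). Of the cartilage genes always tested, Col2a1 (-0.69 ± 0.26), Acan (0.36 ± 0.47), Mmp13 (-0.23 ± 0.24) and Col10a1 (0.47 ± 0.37) were not called between 8 and 40 weeks. With those 2 arrays left out Acan was at 0.97, Mmp13 at 0.05 and Col10a1 at 0.95, again with none called. With single arrays left out they ranged from 0.07 to 0.84, -0.46 to 0.08 and 0.19 to 0.76.

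In Str/ort, 7 genes rose and 3 fell between 8 and 18 weeks (n = 3 and 4 arrays). The transcription factor gene Zbtb16 rose by 1.55 ± 0.23, Fkbp5, a chaperone of the glucocorticoid receptor, by 1.43 ± 0.20, Tsc22d3, which encodes the leucine zipper protein GILZ, by 1.28 ± 0.23, and the clock gene Per1 by 1.19 ± 0.19 (adjusted p = 0.00819, 0.00819, 0.0363 and 0.0111). Nr4a3 (1.32 ± 0.24), the heat shock gene Hspa1a (1.08 ± 0.20) and Fzd1 (0.73 ± 0.11) rose too, and Jhy (-0.62 ± 0.11), Elp4 (-0.55 ± 0.10) and Prorp (-0.53 ± 0.09) fell. Of 28 immediate early and heat shock genes 1 rose and 27 were not called, and 8 were called over the list alone, with a median of 0.34 and adjusted p = 0.487 with an estimated correlation. Of 18 circadian clock genes 1 rose, and 4 were called over the list alone, with a median of 0.34 and adjusted p = 0.488 with an estimated correlation. Of 29 cell cycle genes none was called over all genes and 3 were over the list alone, with a median of -0.39. Of 23 interferon response genes none was called over all genes and 10 were over the list alone, all lower, with a median of -0.50 (adjusted p = 0.582 for both with an estimated correlation). Muscle markers had a median of 0.89 and erythroid markers one of -0.31, with none called.

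These 10 genes, 7 higher and 3 lower, were all that limma called, and 2494 had an unadjusted p under 0.05. The count was 5, 1 and 0 without Str/ort 8 weeks replicates 1, 2 and 3, and 3, 2 and 42 without Str/ort 18 weeks replicates 1, 2 and 4. Every one of them lost its call without 8 weeks replicate 3 (adjusted p up to 0.395), and all but Fkbp5 also without 8 weeks replicate 2. Without the 2 CBA arrays that stood apart, which enter only through the shared variance, 1669 genes were called, 344 higher and 1325 lower, including these 10, so the excess of higher genes did not hold there. The count was 3117 with array weights, 574 on the 2 groups alone, 5 with the replicate number as a block and 34 with the muscle and erythroid means as covariates. Camera called 16 lists, and none with an estimated correlation (lowest adjusted p = 0.487, 2 lists with an unadjusted p under 0.05).

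From 8 to 40 weeks in Str/ort, Ifit1 fell by 1.63 ± 0.24 (adjusted p = 0.00534) whichever array was left out, Rtp4 by 1.43 ± 0.30, Ifit3 by 1.35 ± 0.32 and Ifit2 by 0.77 ± 0.18. Of 23 interferon response genes 8 fell, none rose and 15 were not called, and 17 were called over the list alone, with a median of -0.62. Camera gave the list adjusted p = 2.08e-14, or adjusted p = 0.949 with an estimated correlation. Igll1 (-0.99 ± 0.19), Ebf1, a B cell transcription factor (-0.86 ± 0.14), Vpreb3 (-0.96 ± 0.20) and Dntt, the polymerase that edits antigen receptor joints (-1.17 ± 0.23), fell. Jchain (1.39 ± 0.23), Igkv6-20 (1.88 ± 0.33) and Igkv8-30 (1.26 ± 0.30) rose. Of 18 lymphocyte markers 2 rose, 3 fell and 13 were not called, and 12 were called over the list alone, with a median of -0.40 and adjusted p = 0.949 with an estimated correlation. The fibroblast genes Dpp4 (-1.05 ± 0.16), Fap (-0.89 ± 0.16) and Pdgfra (-0.62 ± 0.15), the membrane protease gene Mmp16 (-0.90 ± 0.17), Lgr5 (-0.91 ± 0.15) and Npy6r (-1.59 ± 0.27) fell. Snord118, a small nucleolar RNA (2.02 ± 0.43), the opioid precursor gene Penk (1.22 ± 0.25) and Hsd3b6 (1.18 ± 0.26) rose. Muscle markers had a median of 0.38 and erythroid markers one of 0.07, with none called, and Acan (0.90 ± 0.50), Mmp13 (0.01 ± 0.26) and Adamts5 (-0.70 ± 0.20, adjusted p = 0.0751) were not called. Acan was at 0.43 without Str/ort 8 weeks replicate 2, Mmp13 ranged from -0.08 to 0.08 with single arrays left out, and Adamts5 was called without the 2 CBA arrays that stood apart.

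Limma called 302 genes between 8 and 40 weeks in Str/ort, 40 higher and 262 lower. The count was 113, 126 and 3 without Str/ort 8 weeks replicates 1, 2 and 3, and 200, 60 and 52 without Str/ort 40 weeks replicates 1, 3 and 4. Of the 27 called genes named by rule only Ifit1 kept its call in each of these fits, and the other 26 were all lost without 8 weeks replicate 3 (highest adjusted p of any = 0.276). Without the 2 CBA arrays 3504 genes were called, including all 302, and the count was 5432 with array weights, 1897 on the 2 groups alone, 95 with the replicate number as a block and 1868 with the muscle and erythroid means as covariates. Camera called 8 lists, 1 higher and 7 lower, and none with an estimated correlation (lowest adjusted p = 0.949, 1 list with an unadjusted p under 0.05). Between 18 and 40 weeks limma called 0 genes, with 1234 at an unadjusted p under 0.05, 67 without the 2 CBA arrays, and 2, 13 and 2 without Str/ort 18 weeks replicates 3 and 4 and 40 weeks replicate 2. Of 20 synovial fibroblast and tendon markers 10 were called over the list alone in that interval, all lower, with a median of -0.46. Camera called 18 lists there, 3 higher and 15 lower, and none with an estimated correlation (lowest adjusted p = 0.295, 1 list with an unadjusted p under 0.05).

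The 40 against 8 week comparisons of the strains share no arrays. They had 3 rising genes in common, Jchain, Igkv6-20 and Hsd3b6, where 0.0542 are expected for independent lists. They had 12 falling genes in common, where 0.21 are expected: Rag2, Il7r, Il2ra, Igll1, Vpreb3, Lgr5, Fap, Capsl, Jhy, Myl4, Nav3 and Stambpl1. The last 5 of these lie outside the naming rule and are listed because of the overlap. The expected counts are no measure of chance, because genes can vary together and both comparisons use the same variance estimate per gene. Both lists also depend on the fit. The CBA calls were all lost when fitted on its 2 groups alone, and 6 of 35 splits gave as many as its 43. In Str/ort all named genes but Ifit1 lost their call without 8 weeks replicate 3. Across all genes, which are not independent replicates, the changes of the 2 strains had r = 0.11 and rho = 0.015.

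The last question was whether the strains age differently. No gene was called by limma in the 3 tests of the difference between the strains' changes: 0 between 8 and 18 weeks, 0 between 18 and 40 weeks and 0 between 8 and 40 weeks, with 4204, 541 and 2596 genes at an unadjusted p under 0.05. A change called in one strain and not in the other was therefore not shown to differ between them. Erythroid markers had a median difference of -0.72 from 8 to 18 weeks, with 0 of 14 called over all genes and 11 over the list alone. Cell cycle genes had a median difference of -0.58 in that interval, with 0 of 29 called over the list alone. Interferon response genes had a median of -0.49 from 8 to 40 weeks, with 3 of 23 called over the list alone. Over the same intervals the muscle markers had median differences of 1.77 and 2.15, with none called. Camera called 6, 6 and 8 lists in the 3 tests, and none with an estimated correlation (lowest adjusted p = 0.995, 0.511 and 0.941, with 0, 2 and 0 lists at an unadjusted p under 0.05). The second count was 10 without CBA 18 weeks replicate 2, 11 and 12 without Str/ort 18 weeks replicates 3 and 4, 17 without CBA 40 weeks replicate 3 and 11 without Str/ort 40 weeks replicate 1. The last was 5 without CBA 8 weeks replicates 1 or 3 or Str/ort 8 weeks replicate 1 and 4 without Str/ort 40 weeks replicate 1. Without the 2 arrays that stood apart limma called 281, 0 and 157 genes, with array weights 1059, 0 and 391, and without CBA 18 weeks replicate 3 it called 1 gene in the first test.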

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

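The tests of muscle carried into the samples, of single arrays, of the bone marrow share and of compressed signal below were chosen only after the results were seen, while the test across ages, the muscle covariate and the relation of cell cycle to erythroid genes were set before.

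In 16 of 200 groups of 4 arrays, 1 array lay far from the others by Dixon's test, where chance gives 10. CBA 40 weeks replicate 3 accounted for 5 of them: highest for oxidative phosphorylation (11.90), glycolysis (11.04) and skeletal muscle markers (12.13), lowest for neutrophil (12.06) and lymphocyte markers (9.11). The other glycolysis values far above their groups were 10.65 in CBA 8 weeks replicate 4 and 10.78 in CBA 18 weeks replicate 4. Lowest in their groups were matrix proteases in Str/ort 18 weeks replicate 4 (10.08), the Wnt pathway in CBA 8 weeks replicate 3 (8.34), adipocyte markers in Str/ort 40 weeks replicate 1 (8.37), neutrophil markers in Str/ort 18 weeks replicate 3 (12.46), endothelial markers in Str/ort 40 weeks replicate 3 (9.32) and Adamts5 in CBA 8 weeks replicate 1 (9.24). Highest were cell cycle genes in Str/ort 40 weeks replicate 4 (11.11), Col2a1 in Str/ort 18 weeks replicate 3 (11.38) and Mmp13 in CBA 18 weeks replicate 1 (11.32).

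For the difference between the strains' changes with age, camera called several lists with the preset correlation and none with an estimated correlation (lowest adjusted p = 0.511). Splits of the arrays, the real one included, gave as many lists in 97, 99 and 74 of 100 cases for the 3 tests. The medians below are therefore not shown to differ from chance. From 8 to 18 weeks the median differences, Str/ort minus CBA, were 0.39 for collagens, -0.58 for cell cycle, -0.44 for interferon response, -0.26 for senescence and stress response, 1.77 for muscle markers and -0.72 for erythroid markers. From 18 to 40 weeks they were -0.15 for oxidative phosphorylation, 0.45 for cell cycle, -0.31 for circadian clock, 0.57 for erythroid markers, 0.22 for neutrophil markers and -0.15 for pericyte and smooth muscle markers. Without the 2 arrays that stood apart, the named oxidative phosphorylation genes went from -0.33 to 0.02 (Ndufs1) and from -0.29 to -0.09 (Ndufs4). The named neutrophil genes went from 0.45 to 0.22 (Fcnb) and from 0.35 to 0.17 (Ctsg), while the clock gene Per1 stayed at -0.78. From 8 to 40 weeks they were 0.24 for collagens, -0.16 for oxidative phosphorylation, -0.49 for interferon response, -0.21 for senescence and stress response, 2.15 for muscle markers, -0.40 for adipocyte markers, 0.18 for neutrophil markers and -0.17 for endothelial markers. With those arrays left out, Ndufv1 went from -0.50 to -0.13, Sdhd from -0.45 to -0.13, Cxcr2 from 0.38 to 0.13 and Pglyrp1 from 0.28 to 0.07. By contrast, Ifit1 went from -1.27 to -1.41 and the muscle gene Myot from 3.21 to 4.56. Among transcript clusters outside the comparisons, 716 of 11799 without a gene name and 195 of 1321 with several names were called for the strain average.

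Muscle markers were lower in Str/ort at 8 weeks in all 3 arrays (difference of means -2.22, exact permutation p = 0.0286, the smallest possible). Within groups 95.2% of the variance of the markers lay on 1 component, against a median of 46.4% for random lists, as muscle carried in by dissection would give. CBA 8 weeks replicate 1 alone does not explain it, since the median difference without that array is -2.35. A difference of the strains at every age stays open: the differences at 18 and 40 weeks were -0.69 and -0.31, with permutation p = 0.0696 over the 3 ages. The 40 week value rests on CBA 40 weeks replicate 3, at 12.13 where the other CBA arrays of that age were at 8.20, 8.05 and 7.75. Without the 2 arrays that stood apart the median difference at 40 weeks was above 0, as given in the results.

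Erythroid markers were lower in all 4 Str/ort arrays at 18 weeks. A smaller share of bone marrow would also lower neutrophil markers, but the 4 such markers under log2 12 differed by 0.06 (exact permutation p = 0.6), against -0.95 for 10 erythroid markers (exact permutation p = 0.0286). Lymphocyte markers were lower too, by 0.38 (exact permutation p = 0.0286), and macrophage markers differed by 0 (exact permutation p = 1). The markers thus did not fall equally, which goes against an equal loss of all marrow cells as the only change. A smaller marrow share stays open, since a strain difference in neutrophil genes could hide it and 4 markers are few. A loss of some marrow cells stays open too. With the muscle mean as a covariate the erythroid difference was -0.95, so it did not shrink. Muscle markers were themselves lower in Str/ort at 18 weeks (difference of means -0.69, exact permutation p = 0.429). More muscle in Str/ort was therefore not seen. An adjustment for muscle could then hardly shrink the erythroid difference, so this fit by itself does not exclude muscle. Cell cycle genes followed the erythroid mean within groups (r = 0.929, rho = 0.92, permutation p = 0.00002 over 23 arrays; r = 0.864 without the 2 farthest arrays), so the lower cell cycle genes may come from dividing erythroid precursors. Their relation to other marrow markers was not tested, so other dividing marrow cells are not told apart from these.

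CBA 8 weeks replicate 1 and CBA 40 weeks replicate 3 stood apart from their groups. In the latter muscle markers were 4.63 above the group, which fits muscle in the sample. The SD of its difference was 0.625 without those markers and 0.656 with them. So few genes can hardly change an SD over all genes, so these values do not speak against muscle. That array had 275 genes over 2 log2 units above the group, 32 of them muscle markers. Its r of difference with mean level, -0.28, lies within the other arrays. In the former muscle was 0.78 above the group, too little to explain it, and the difference from the group fell with mean level (r = -0.575, other arrays -0.39 to 0.51), as compressed signal would give. H2-Ea was at 12.73 and 11.56 in these 2 arrays, against 6.84 and 7.18 in Str/ort of those ages, so neither was a Str/ort sample; this bound was changed after the results were seen, because under the first one, within 1 log2 unit of the other CBA arrays (12.63), the second array would have stayed undecided although it lies far above Str/ort.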

How the results depend on the processing

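Of 358 called results of named genes, 234 kept their call under every alternative set beforehand other than leaving out arrays, 204 whichever array was left out, and 354 without the 2 arrays that stood apart. No direction turned except with the muscle and erythroid means as covariates (15 turned). The cause of the changes was not tested, except that leaving out arrays or genes changes what is tested. Comparisons are listed in this order: strain at 8, 18 and 40 weeks and on average; CBA 18 against 8, 40 against 18 and 40 against 8 weeks; Str/ort likewise; and the differences between strains likewise.

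Genes called ranged, with single arrays left out, over 140 to 488, 687 to 1755, 472 to 1700, 2296 to 4617, 0 to 5, 0 to 2, 4 to 1620, 0 to 42, 0 to 13, 3 to 224, 0 to 1, 0 to 0 and 0 to 0, and lists called over 12 to 16, 14 to 21, 14 to 18, 19 to 23, 9 to 14, 8 to 21, 6 to 14, 11 to 19, 14 to 20, 7 to 11, 5 to 8, 5 to 17 and 4 to 11. With array weights the genes called were 1421, 6218, 4624, 7857, 113, 13, 1410, 3117, 342, 5432, 1059, 0 and 391. Without the 2 arrays that stood apart they were 771, 5150, 3929, 7004, 188, 3, 954, 1669, 67, 3504, 281, 0 and 157, and lists of the second difference between strains were 15. On the groups of the comparison alone they were 4169 and 189 for strain at 18 and 40 weeks, 1 and 0 for CBA 18 and 40 against 8 weeks, and 574 and 1897 for Str/ort 18 and 40 against 8 weeks. With the muscle covariate they were 2661 and 1111 for strain at 18 and 40 weeks, 461 for CBA 40 against 8 weeks, and 28 and 6 for Str/ort 18 against 8 and 40 against 18 weeks. With both covariates they were 221, 2032 and 1906 for strain at 18 and 40 weeks and on average, 1298 for CBA 40 against 8 weeks, 34 and 1868 for Str/ort 18 and 40 against 8 weeks and 13 for the last difference between strains. Without the dimmest genes they were 79 for CBA 40 against 8 weeks and 16 and 2 for Str/ort 18 against 8 and 40 against 18 weeks, where fewer genes are tested.

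Quantile normalization gave 88 genes for CBA 40 against 8 weeks. It moved the split of higher and lower genes from 541 and 1201 to 767 and 1066 at 18 weeks and from 243 and 471 to 445 and 485 at 40 weeks, so the size of the excess of lower genes depends on the scaling. With an estimated correlation 0 lists were called in each of the 13 comparisons, and with exact permutation 0 in each of the 9 tested, but the design leaves little room for a call: the smallest possible p, 0.0286, passes adjustment only where 17 or more lists reach it, and at most 8 were under 0.05. With the replicate number as a block 5 and 95 genes were called for Str/ort 18 and 40 against 8 weeks. The values do not show that the numbers pair samples: 13 of 33 pairs correlated over 0.1 (range -0.603 to 0.587), and in 0 comparisons did all pairs. With so few arrays per group they do not exclude a pairing either.

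With both covariates these turned: at 18 weeks Rrm2 to 0.084, Mcm2 to 0.078, Nqo1 to 0.123, Gadd45a to 0.099, Asns to 0.113, Trim10 to 0.046, Epor to 0.088, Tspan33 to 0.025 and Mcam to -0.001; on average Sox9 to -0.161, Col10a1 to -0.02, Cenpf to 0.012, Epb42 to 0.008, Epor to 0.033 and Gjc3 to -0.232. Trim10, Epor, Tspan33 and Epb42 are part of the erythroid mean, so this fit is no test of them. Its erythroid slope also leans on the arrays that stood apart, as given in the results. A fit on the groups alone is not a separate fit for the strain average, and every cluster on its own was not run for single genes.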

Other observations

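The test of glucocorticoid response genes below was set before its result was seen, and that of neighbouring genes only after the strain differences were seen.

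Fkbp5, Zbtb16, Tsc22d3 and Per1, which rose in Str/ort between 8 and 18 weeks, are known to respond to glucocorticoids. Of 24 other such genes 22 were measured; their median change was 0.49, 19 were above 0, 14 were called over that list alone and 0 over all genes, with Ddit4 at 1.26 ± 0.24 (adjusted p = 0.0631) and Klf9 at 1.10 ± 0.27 (adjusted p = 0.16). The mean per array gave an exact permutation p = 0.0571, the smallest possible but 1 with 3 and 4 arrays, so a glucocorticoid response, as stress or time of day at collection could give, stays open. Camera on that list gave p = 0.00471 with an estimated correlation, and without the 2 arrays that stood apart 14 of the genes were called over all genes, but the bound set before asked for an exact permutation p under 0.05. In CBA the median was 0.09 over the same ages (exact permutation p = 0.0857).

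Of 156 genes that differ between the strains in the same direction at all 3 ages, 15 had a called neighbour, against a mean of 2.47 and a highest value of 16 in 1000 shuffles, a ratio of 6.07. Genes that changed between 8 and 40 weeks in Str/ort gave 24 of 302, against 9.19 (ratio 2.61). Chromosome segments that differ between the strains could give this, but the test left it open because 1 of the shuffles gave as many. The bound for excluding it was changed after the result was seen: under the first, any value inside the range of the shuffles, 15 would have excluded the explanation, although only 1 shuffle in 1000 reached it. Of the 15 genes 7 are neighbours from the same families (Chit1 and Chil1, Ifi203 and Ifi202b, and Ly6i, Ly6a2 and Ly6g), whose probes can share signal, so the count rests in part on such families. Whether shared signal or sequence variants under the probes contribute was not tested.

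The groups were also divided in other ways, to ask whether chance could give the counts: in all 35 ways for 2 groups, and in the real way and others drawn at random, 100 in all, for the strain average and the differences between strains. For genes, the real split of the strain comparison was the only 1 of 35 with as many at 8 weeks (347, highest other 44), 18 weeks (1742, highest other 0) and 40 weeks (714, highest other 454), and the only 1 of 100 for the average (3009, highest other 1), as was that of Str/ort 40 against 8 weeks (1 of 35; 302, highest other 1). For Str/ort 18 against 8 weeks 2 of 35 gave as many as 10 (highest 34), and for CBA 40 against 8 weeks 6 of 35 gave as many as 43, with 3837 for 1 split, which points to structure among the samples other than age. Chance cannot be excluded for these. Where the real count was 0 every split gives as many, so the splits say nothing about chance: CBA 18 against 8 weeks (35 of 35, highest 22), CBA 40 against 18 weeks (35 of 35, highest 1), Str/ort 40 against 18 weeks (35 of 35, highest 1) and the differences between strains (100 of 100 each, highest 54, 46 and 257).

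For lists, only the strain average met the prior bound of fewer than 0.05 of splits with as many (22 lists, 2 of 100, highest 22). A split other than the real one also gave 22 lists, and none of them was called with an estimated correlation (lowest adjusted p = 0.305). Chance is therefore not excluded there either. As many lists came from 9, 10 and 10 of 35 splits for strain at 8, 18 and 40 weeks (13, 18 and 17 lists; highest 16, 22 and 20), 13, 26 and 23 of 35 for CBA 18 against 8, 40 against 18 and 40 against 8 weeks (highest 19, 22 and 20), 16, 11 and 30 of 35 for Str/ort likewise (highest 22, 20 and 24), and 97, 99 and 74 of 100 for the differences between strains (highest 22, 21 and 22).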
